A study of Mus musculus with 3 samples.

How the data were processed

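The samples were 3 separate cultures of the mouse line Ba/F3, grown in RPMI with fetal calf serum, antibiotics and recombinant murine IL-3, per the labels' protocols. Total RNA was purified on columns, polyadenylated RNA was made into libraries with a strand-marking kit, and 50-base single-end reads were taken on an Illumina NovaSeq system. Per the series' design text, the authors aligned the reads to GRCm38 with HISAT2, using its ready-made index with variants and transcripts, and counted reads with the in-house program GenSum. The submitters' processing notes also name HISAT2 and GRCm38. Versions, the strand setting of the counting, the handling of reads with several matches and the annotation release are not given in the sources used here.

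The deposited table has 55486 rows, each with a gene identifier, a log2 value for each culture, the authors' average, and a symbol with coordinates. The authors' deposited log2 values are log2(reads per 10000000 + 1), since undoing the log made each column sum to 10000000. Dividing the linear values by the value of a single read gave whole numbers for 100% of entries within a tolerance of 0.01, with totals of 32044889, 33880292 and 37180883 reads. A read was thus worth 0.0312, 0.0295 and 0.0269 CPM in cultures 1, 2 and 3, and 3 reads, taken as the limit that a count of 0 allows, 0.0936, 0.0885 and 0.0807 CPM. Reads carry no molecular identifiers, so limits and intervals cover counting error only.

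In none of the 23001 rows with reads do the gene identifier and the symbol name the same gene: the matching count is 0. The columns of cultures 1 and 2 follow the identifiers, and the column of culture 3 follows the symbols and coordinates. Culture 3 was therefore matched to the other cultures by exact gene coordinates in GENCODE M21 (GRCm38) for 54916 rows and by a symbol naming 1 gene for 345 rows. The other 225 rows had no match, and 55196 genes were joined and analysed. The authors' average is the mean of each row in 100% of rows, so it mixes genes and was not used for any level. This step was chosen after the data were seen; values on the rows as deposited are an alternative in the closing section.

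Reads were scaled to the sum of each column and given as CPM. A gene was detected at 1 or more CPM in all 3 cultures. Logs are log2(CPM + 1), with a pseudocount of 1. Spread between cultures was compared with counting noise by a chi-square test of Poisson heterogeneity for each gene with a mean of at least 10 reads, adjusted by Benjamini-Hochberg with a threshold of 0.05. That test compares these libraries and not conditions, and an adjusted p rests on 1 library per culture. The design fixed before the data were examined assumed read counts and named a common dispersion from a count model. The deposited unit is log2, so the planned count package was not used. A common negative binomial dispersion was fitted to the recovered reads instead, with an intercept, library sizes and a Cox-Reid adjusted likelihood, after the other results were seen. The coefficient of variation beyond counting noise over genes with at least 100 reads is given beside it.

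Before the data were examined, 25 function lists and 8 cell type marker lists with 469 entries were fixed, of which 468 were measured. Detection in each list was tested against all other named genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 33 lists. The level of lists with at least 5 detected members was set against 10000 random lists of detected genes, and the deviation in each culture against 10000 random lists matched on mean expression in 20 bins. The genes named were also fixed by rule: 7 genes tied to the study, the 10 highest means, the 3 highest detected members and up to 3 undetected members of each list, and the 10 detected genes with a mean of at least 10 CPM and the largest ratio between cultures. Where a symbol names more than 1 gene (Aldoa and Ddit3), the gene with more reads was used.

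The test and the matching were tried on simulated Poisson reads for 13151 tested genes with the means and library sizes of these cultures. Changes in 1 culture by 1.2, 1.5, 2 and 4 times in 50 genes each were called for 64.0%, 68.0%, 76.0% and 90.0% of them, unchanged genes for 0.0464%, and shuffled rows were rejoined for 100% of genes. The shuffled rows were built from the annotation used for the matching, so this checked the code and not real rows without a coordinate match. These Poisson reads carried counting noise only. A simulated dispersion of 0.01 was recovered as 0.00998. Alternatives covered detection thresholds of 0.5 and 5 CPM, detection in at least 1 culture, trimmed mean of M values and median-of-ratios scaling, values divided by transcript length, pseudocounts of 0.1 and 5, read minimums, protein-coding background, removal of a quadratic trend in GC content and log length from the list deviations, and leaving out each culture. Scaling by the values as deposited was not run apart, since the columns already sum to 10000000. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.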

Results

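Ba/F3 is a mouse haematopoietic line that grows only while interleukin-3 (IL-3) is supplied. Polyadenylated RNA from 3 separately grown cultures, all kept in recombinant murine IL-3, was sequenced as strand-marked libraries. The samples form 1 group and hold no contrast between conditions. The data thus describe which genes this cell line expressed and how far the cultures differed. The study concerns IgA antibody-mediated killing of tumour cells by neutrophils, and the inositol phosphate kinase ITPK1 in that process. The gene counts summed to 32044889, 33880292 and 37180883 reads in cultures 1, 2 and 3. A single read equalled 0.0312, 0.0295 and 0.0269 CPM, and a gene without a read lay below 0.0936, 0.0885 and 0.0807 CPM (3 reads, counting error only). Levels below are CPM (reads of a gene scaled to the sum of reads of its culture), given as mean ± SD over the cultures (n = 3). They are not corrected for transcript length, so levels of different genes compare read yield and not molecules.

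Of 55196 genes measured in all cultures, 10991 reached at least 1 CPM in every culture and were counted as detected. Of these, 10078 were protein-coding, which is 45.9% of the 21958 protein-coding genes. Detected genes had a median of 39.7 CPM; 8827 had a mean of at least 10 and 2468 of at least 100. Protein-coding genes took 98.4 ± 0.0941% of the reads, ribosomal protein genes 6.99 ± 0.290% and the 10 most abundant genes of each culture 5.36 ± 0.0790%.

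Culture 3 stands in another row order than cultures 1 and 2 in the deposited table, so its values were matched to the others by gene. Among 120 genes above 13 on the deposited log2 scale, culture 3 differed from the mean of cultures 1 and 2 by a median of 0.66 on the same rows. Matched by gene, it differed by 0.058, beside 0.051 between cultures 1 and 2. The row with the symbol Itpk1 carries the gene identifier of Tmsb4x, and the authors' average on it corresponds to 771 CPM, 11.3 times the matched Itpk1 mean.

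**Figure D1:**
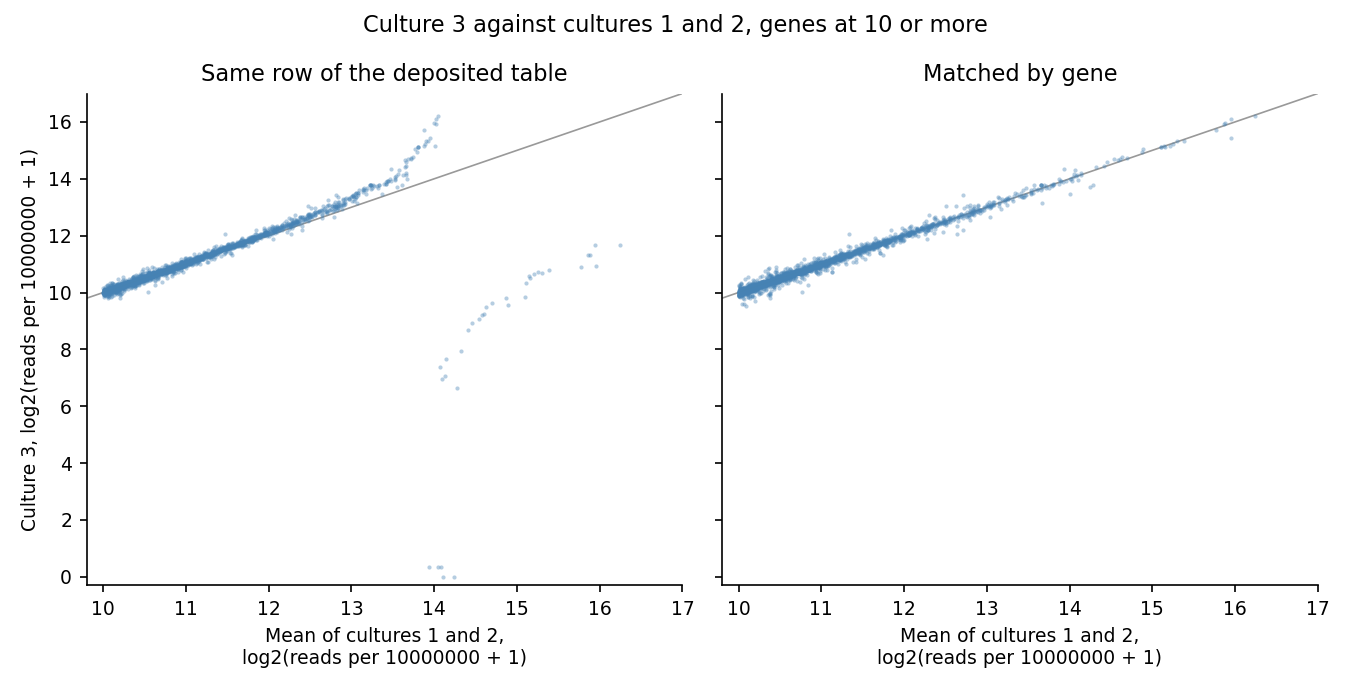
Culture 3 against the mean of cultures 1 and 2, both in log2(reads per 10000000 + 1), for genes with a mean of at least 10 on that scale; each point is a gene and the line marks equal values. On the same rows of the deposited table (left) 36 of the 120 genes above 13 differed by more than 2, and after matching by gene (right) 0 did.

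Itpk1, which encodes the kinase that phosphorylates inositol tris- and tetrakisphosphates (ENSMUSG00000057963, chromosome 12, 102568582 to 102704930, minus strand), was expressed at 65.8, 66.9 and 71.2 CPM in cultures 1, 2 and 3, or 68.0 ± 2.85. It stood at the 66.3 percentile of detected genes. Cd47, the "don't eat me" ligand of the myeloid inhibitory receptor SIRPα (chromosome 16, 49800533 to 49915010, plus strand), was among the most abundant transcripts at 1167, 1197 and 1175, a mean of 1179.7 ± 15.3 and the 99.4 percentile. Qpctl, the glutaminyl cyclase that forms the pyroglutamate on CD47 (chromosome 7, 19139702 to 19149291, minus strand), lay far lower at 13.3, 15.0 and 14.3, a mean of 14.2 ± 0.823 and the 25.3 percentile. The Cd47 value was 83.3 ± 3.90 times the Qpctl value. The secreted cyclase gene Qpct had no read in any culture.

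The IL-3 receptor chains were read at unequal levels. Csf2rb, the common β chain (chromosome 15, 78325752 to 78353847, plus strand), stood at 741, 725 and 698 CPM, a mean of 721 ± 21.7 and the 98.6 percentile, and Il3ra, the α chain (chromosome 14, 14346275 to 14356011, plus strand), at 28.2, 27.3 and 38.7, a mean of 31.4 ± 6.37 and the 43.2 percentile. The ratio of Csf2rb to Il3ra was 23.6 ± 4.86. Csf2rb2, a near-identical neighbouring copy named here after its values were seen, stood at 675 ± 21, so the split of reads between both β chain genes is uncertain. Trp53, the p53 gene (chromosome 11, 69580359 to 69591873, plus strand), was at 112, 104 and 103, a mean of 106 ± 4.95 and the 79.1 percentile. Erbb2, the gene of the HER2 receptor (chromosome 11, 98412470 to 98437716, plus strand), was not detected, at 0.0936, 0.0590 and 0.134 CPM and a mean of 0.0957 ± 0.0378, close to the limit set by depth.

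Among these genes, the chi-square test of Poisson heterogeneity with Benjamini-Hochberg adjustment found differences between the cultures beyond counting noise for Il3ra (adjusted p = 3.9e-19, highest to lowest culture 1.42 times), Csf2rb (adjusted p = 1.7e-09, 1.06 times), Trp53 (adjusted p = 0.00231, 1.09 times), Cd47 (adjusted p = 0.00571, 1.03 times) and Itpk1 (adjusted p = 0.0463, 1.08 times), but not for Qpctl (adjusted p = 0.356, 1.12 times). Qpctl had a larger ratio than Csf2rb, Trp53, Cd47 and Itpk1 but fewer reads. It had 427, 507 and 531 reads in cultures 1, 2 and 3, against 37394, 40545 and 43702 for Cd47. The missing call thus does not show that Qpctl was steadier. Culture 3 had the highest Il3ra level, and the chi-square test without it gave an adjusted p of 0.708. By the same chi-square test the Csf2rb call also ended without culture 3 (adjusted p = 0.0625) and the Trp53 call without culture 1 (0.851). The Cd47 chi-square call ended without culture 1 (0.0710) or 2 (0.493), and the Itpk1 call without culture 1 (0.158) or 3 (0.790) or with no minimum read count (0.0793).

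**Figure D2:**
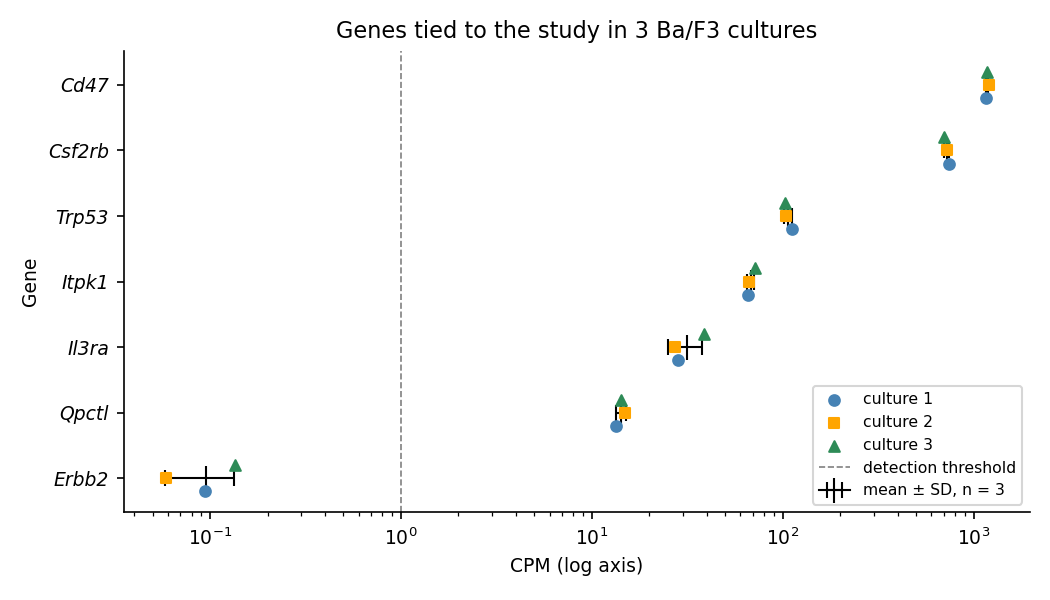
CPM (log axis) of the 7 genes tied to the study; coloured points are cultures 1, 2 and 3, vertical ticks the mean and bars the SD. Cd47 lies near 1179.7, Itpk1 near 68.0 and Erbb2 below the detection threshold of 1 (dashed line).

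The inositol phosphate pathway was expressed almost in full. Of 22 kinases, phosphatases and related genes on the list fixed in advance, 21 were detected, beside 19.9% of all other genes (Fisher's exact test, adjusted p = 5.5e-13). Among other protein-coding genes 45.8% were detected (exact test, adjusted p = 1.1e-05). Inpp5d, which encodes the SHIP1 phosphatase, led at 232 ± 3.61, followed by the inositol monophosphatase gene Impa2 at 154 ± 5.57 and the inositol hexakisphosphate kinase gene Ip6k1 at 122 ± 14.1. Ip6k3 was not detected, with a mean of 0.00897. Itpk1 was 2.59 ± 0.0598 times Ippk, whose enzyme makes inositol hexakisphosphate; that gene was picked after its values were seen. Upstream, 7 of 12 phospholipase C and IP3 receptor genes were detected. Plcg2 had 341 ± 9.28, Plcb2 274 ± 25.1 and Itpr1 162 ± 4.34 CPM, while Plcb1 (0.00897), Plcb4 (0.00984) and Plcd1 (0.0208) were not detected. That list passed against all genes (exact test, adjusted p = 0.00660) but not against protein-coding genes (exact test, adjusted p = 0.554).

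All 17 genes of the IL-3 receptor and signalling list were detected (Fisher's exact test, adjusted p = 8.0e-12). Pim1, a STAT5 target kinase gene, stood at 1125 ± 72, Jak1 at 776 ± 17.4 and Csf2rb at the level above. The median over the list, 180.2 CPM, lay at percentile 100 among 10000 random lists of detected genes. Percentile 100 was also reached by the ferroptosis, proliferation, housekeeping, glycolysis and mitochondrial lists, so it is not particular to IL-3 signalling.

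Of 16 adhesion ligands and integrins, 14 were detected (Fisher's exact test, adjusted p = 4.0e-08), led by Itga4 at 511 ± 34.1, Itgb1 at 448 ± 16.3 and Cd44 at 328 ± 5.54. Vcam1 had no read and Itgal, the LFA-1 α chain gene, averaged 1.14 with culture 1 below the threshold. All 14 MHC class I presentation genes were detected (exact test, adjusted p = 7.2e-10), led by the chaperone genes Calr (1538 ± 31.8), Canx (842 ± 18.6) and Pdia3 (713 ± 22.2). Of 9 MHC class II genes, 5 were detected at a low median of 5.38, percentile 1.69 of random lists. H2-DMb1 (26.7 ± 0.925), H2-DMa (7.25 ± 0.0647) and H2-Oa (5.38 ± 0.730) led, H2-Aa and H2-Ab1 had no read, and H2-Eb1 averaged 0.0474. That list passed against all genes (exact test, adjusted p = 0.0276) and not against protein-coding genes (exact test, adjusted p = 0.840).

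Of 16 checkpoint ligand genes, 9 were detected. Vsir, which encodes VISTA, was highest at 287 ± 7.18, then Tnfrsf14 at 39.1 ± 4.08 and Cd274, the PD-L1 gene, at 27.5 ± 1.63. Cd86 had no read, and Cd276 (0.156) and Vtcn1 (0.00984) were not detected. The list passed against all genes (Fisher's exact test, adjusted p = 0.00261) and not against protein-coding genes (adjusted p = 0.605). Only 5 of 12 Fc receptor genes (exact test, adjusted p = 0.0942) and 3 of 9 complement regulator genes (exact test, adjusted p = 0.457) were detected, and neither list passed. With a detection threshold of 0.5 CPM the Fc receptor list passed against all genes (log2 odds 2.33, beside 1.56). Against protein-coding genes at the main threshold its log2 odds were -0.210. Fcgr3 (111 ± 2.47), Fcer1g (79.0 ± 2.90) and Fcgr2b (46.4 ± 1.55) led the Fc receptors. Fcgr1 (0.848) and the neonatal Fc receptor gene Fcgrt (0.832) were not detected, and Fcer1a had no read. Cr1l (42.3 ± 0.826), Clu (22.8 ± 1.30) and Cd46 (2.80 ± 0.502) were the complement regulators detected, while Cd55, Cd55b and Cd59a had no read. Of 18 sialic acid and glycan synthesis genes, 16 were detected (exact test, adjusted p = 2.5e-09). Fut8, the core fucosyltransferase gene, led at 869 ± 11, with the sialyltransferase genes St3gal4 at 261 ± 13.6 and St3gal2 at 209.5 ± 10.1. Nanp averaged 0.0871 and St3gal6 had no read.

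Of 28 apoptosis genes, 24 were detected (Fisher's exact test, adjusted p = 1.4e-12), led by the anti-apoptotic genes Mcl1 at 478 ± 13.8 and Bcl2 at 323 ± 4.93. The BH3-only genes Bik and Hrk and the effector gene Bok had no read. Of 13 necroptosis and pyroptosis genes, 9 were detected (exact test, adjusted p = 3.5e-04, and 0.187 against protein-coding genes). Gsdmd, the pore-forming gasdermin D gene, stood at 84.1 ± 7.27, Ninj1 at 69.1 ± 6.04 and Aim2 at 53.6 ± 6.27. The necroptosis kinase gene Ripk3 (0.00984), Gsdmc (0.0194) and Gsdme (0.135) were not detected. Of 23 ferroptosis and oxidant defence genes, 22 were detected (exact test, adjusted p = 2.3e-13), with the ferritin genes Ftl1 at 1149.7 ± 75.6 and Fth1 at 481 ± 4.94, the transferrin receptor gene Tfrc at 584 ± 15.6, and Alox15 not detected (0.0763).

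Of 12 p53 pathway and tumour suppressor genes, 10 were detected (Fisher's exact test, adjusted p = 1.1e-05). The p53 targets Ccng1 (746 ± 17.9) and Cdkn1a (505 ± 13.6) led. Cdkn2a, which encodes p16 and p19ARF, had no read in any culture, and its neighbour Cdkn2b averaged 0.0188. Among the 4 ERBB receptor genes only Erbb3 was detected, at 4.81 ± 0.595 (exact test, adjusted p = 0.627). Egfr had no read and Erbb4 averaged 0.0104.

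Eef1a1 (7715 ± 126) and Eef2 (6538 ± 424), both elongation factor genes, were the most abundant transcripts, followed by the aldolase gene Aldoa (6172 ± 257, ENSMUSG00000030695), Actb (6039 ± 148), the mitochondrial cytochrome oxidase gene mt-Co1 (5712 ± 1385) and the glucose phosphate isomerase gene Gpi1 (5549 ± 144). Ly6e (4231 ± 96.7), the desaturase gene Scd2 (4054 ± 124), Hsp90ab1 (3867 ± 86.7) and Rpl4 (3745 ± 96.5) completed the first 10. Of 13 glycolysis and hypoxia genes, 12 were detected (Fisher's exact test, adjusted p = 1.1e-07), with Pgk1 at 3627 ± 29.5 and Pkm at 3532 ± 43.6 after Aldoa, and Egln3 not detected (0.0604). Every one of the 18 proliferation genes (exact test, adjusted p = 2.0e-12), the 12 cholesterol synthesis genes (exact test, adjusted p = 1.4e-08) and the 14 housekeeping genes (exact test, adjusted p = 7.2e-10) was detected. Top2a (974 ± 31.3), Mki67 (717 ± 31.7) and Mcm6 (501 ± 4.92) led the proliferation genes, and Srebf2 (431 ± 34.1) was among the cholesterol genes.

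Of 13 unfolded protein and integrated stress response genes, 12 were detected (Fisher's exact test, adjusted p = 1.1e-07), led by Hsp90b1 (1176 ± 22.9), Hspa5 (660.3 ± 19) and Xbp1 (421 ± 11.9), and Chac1 had no read. Of 15 immediate early and heat shock genes, 10 were detected (exact test, adjusted p = 2.6e-04, and 0.205 against protein-coding genes). Hspa8 stood at 1083 ± 29.8, Ier2 at 147 ± 28.2 and Hsph1 at 134 ± 1.58, Fosb (0.846) and Egr1 (0.0584) were not detected, and Atf3 had no read. Of 15 interferon response genes, 9 were detected (exact test, adjusted p = 0.00156, and 0.442 against protein-coding genes), led by Bst2 (90.0 ± 14.1) and Stat2 (75.3 ± 5.97). Isg15 averaged 1.08 with culture 2 below the threshold, and Ifit1 (0.223) and Ifit3 (0.0306) were not detected.

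Mitochondrially encoded mRNAs differed between the cultures more than any other list with a level. They and the mitochondrial RNA genes took 1.68% of the reads in culture 1 (Wilson 95% interval 1.67 to 1.68), 1.31% in culture 2 (1.31 to 1.32) and 1.04% in culture 3 (1.04 to 1.04). The cytochrome oxidase gene mt-Co1 stood at 7148, 5602 and 4385 in cultures 1, 2 and 3, mt-Nd1 at 2241, 1760.2 and 1392 and mt-Cytb at 2203, 1705 and 1351. Of 13 genes, 8 were detected (Fisher's exact test, adjusted p = 0.00234, and 0.426 against protein-coding genes). Values for mt-Atp8 (0.148), mt-Atp6 (1.06) and mt-Co3 (0.923) are uncertain, since parts of the mitochondrial genome have near-identical nuclear copies. The overlap of mt-Atp8 (7766 to 7969) with mt-Atp6 (7927 to 8607) is short and cannot account for the low mt-Atp6 and mt-Co3 values. If reads of these genes were lost, the mitochondrial shares above are too low, which their intervals do not cover. The cause was not tested. Of 6 sex chromosome genes, the Y-linked Ddx3y (100.3 ± 6.10), Eif2s3y (88.9 ± 12.2), Kdm5d (60.1 ± 4.44) and 1 more were detected, while Xist averaged 0.118 and Tsix had no read (exact test, adjusted p = 0.0250, and 0.0861 against protein-coding genes).

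Early B lymphoid genes were nearly absent from the detected set: Cd79b (19.5 ± 1.22) and Cd79a (1.75 ± 0.118) were found among 20 genes, 9 had no read in any culture, Ebf1 among them, and Pax5 averaged 0.0758. Against protein-coding genes this share was low (Fisher's exact test, adjusted p = 0.00274), and against all genes the test was not passed (adjusted p = 0.457). Of 20 granulocyte and monocyte genes, 9 were detected. The neutrophil proteinase 3 gene Prtn3 (140.5 ± 16.4) and the transcription factor genes Spi1 (136 ± 12.4) and Cebpe (124 ± 23.5) led, Elane averaged 0.805, and Ctsg and Cebpa had no read. This share passed against all genes (exact test, adjusted p = 0.0160) and not against protein-coding genes, of which 45.9% were detected beside 45.0% of the list (exact test, adjusted p = 1, log2 odds -0.038).

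Mast cell and basophil genes were detected for 4 of 14 (Fisher's exact test, adjusted p = 0.549). Gata2 stood at 616 ± 22.2, Mitf at 9.14 ± 0.10 and Ms4a2 at 5.46 ± 0.978, and Kit (0.0194), Fcer1a (no read) and Cpa3 (0.0396) were not detected. Of 11 erythroid genes measured, 6 were detected (exact test, adjusted p = 0.0179, and 0.840 against protein-coding genes): Hba-a1 had 182 ± 13.3, Gata1 66.7 ± 0.803 and Klf1 16.3 ± 2.23 CPM. Hbb-bt averaged 1.12 with culture 1 below the threshold, and the split between Hba-a1 and its near-identical copy Hba-a2 (0.152) is uncertain. Itga2b (571 ± 40.1) and Gp9 (3.22 ± 0.328) were the 2 of 10 megakaryocyte genes detected (exact test, adjusted p = 1), with Itgb3 (0.107), Gp1ba (0.168) and Gp1bb (no read) below the threshold.

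Of 17 T cell and NK cell genes, Lck (6.22 ± 0.343), Cd3g (4.18 ± 0.228) and Gzmb (1.76 ± 0.232) were detected (Fisher's exact test, adjusted p = 1), and Cd3e (0.0306), Cd3d (0.0679) and Cd247 (0.0798) were not. Of 14 stem and progenitor genes, 6 were detected (exact test, adjusted p = 0.0591), and those 6 had a high median of 234. Mecom, the gene of the EVI1 transcription factor, reached 932 ± 65.2, Tal1 356 ± 11.3 and Myb 312 ± 12.1, while Cd34 had no read, Flt3 averaged 0.00984 and Ly6a 0.470. Pecam1 (160.2 ± 4.07) was the 1 gene detected of 15 fibroblast, epithelium and endothelium markers (exact test, adjusted p = 0.405, and 0.00648 against protein-coding genes). Col1a1 averaged 0.873, Col3a1 0.00984 and Col1a2 had no read.

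**Figure D3:**
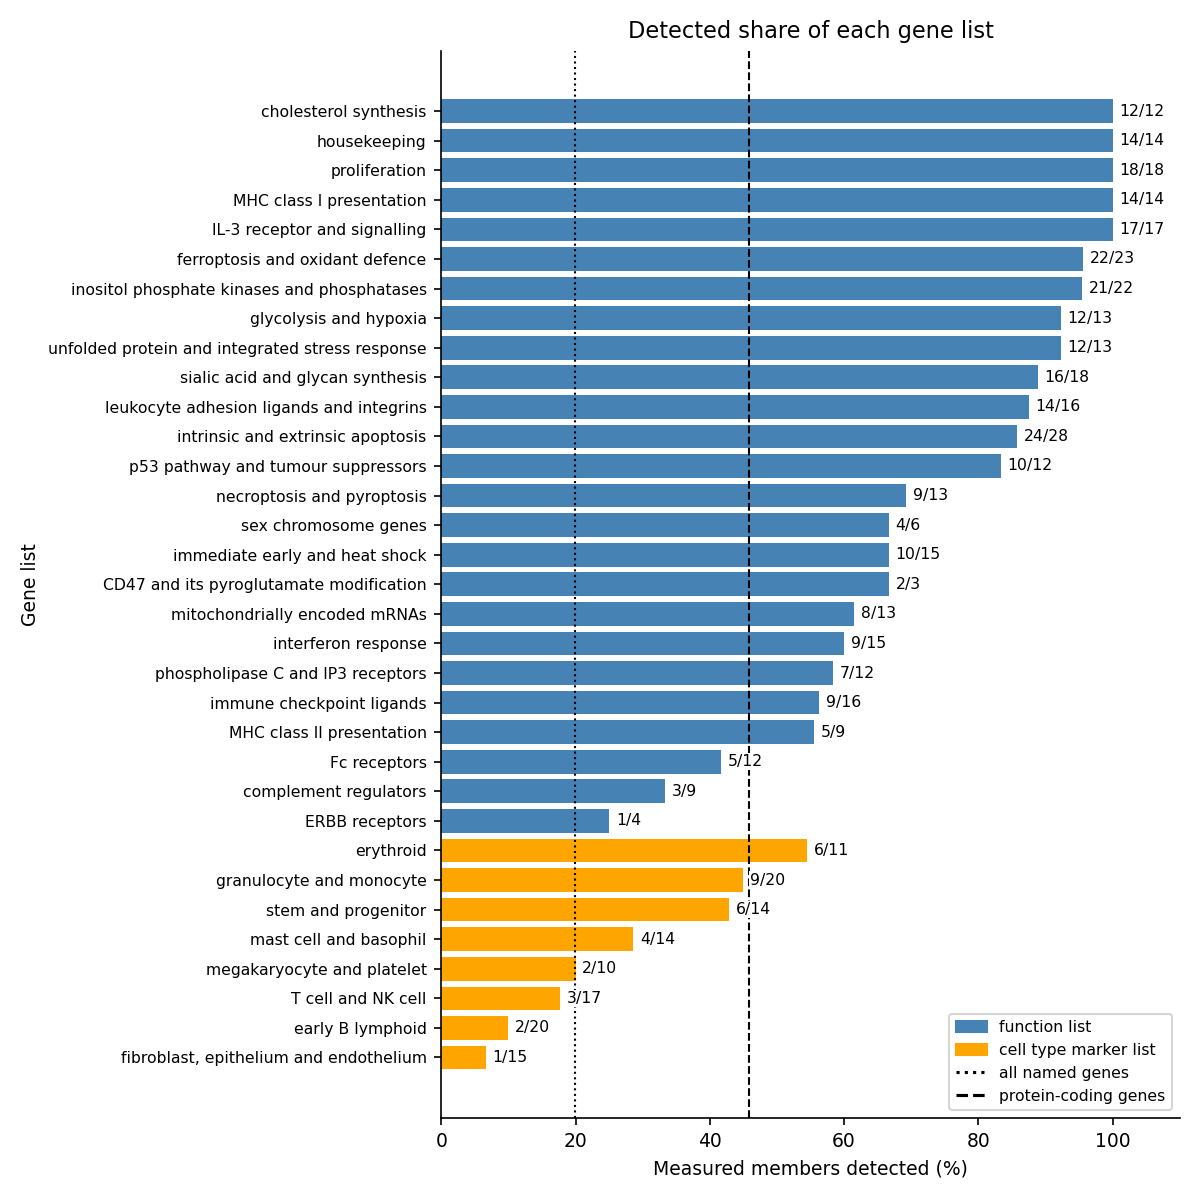
Share of measured members detected (%) for each of the 33 gene lists, with counts beside the bars; blue bars are function lists and orange bars cell type marker lists. The dotted line marks 19.9%, the share over all named genes, and the dashed line 45.9%, the share over protein-coding genes; 5 function lists reach 100%, and the early B lymphoid list 10.0%.

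Of the 33 lists, 23 differed from all other named genes in their detected share and each of these lay above it (Fisher's exact test, adjusted p under the threshold of 0.05). Against protein-coding genes alone, an alternative added after the data were seen, 15 lists passed, 13 above and 2 below. For each of those 13 the adjusted p was larger than against all genes. By the exact test against protein-coding genes it was 1.1e-05 for the inositol phosphate list and 0.0360 for the p53 list. Genes are not independent replicates, so these tests describe the lists within this transcriptome. By level, 12 of the 24 lists with at least 5 detected members lay above the central 95% of random lists and the MHC class II list below it.

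The cultures were close to one another. Over the 10991 detected genes the Pearson correlation of log2(CPM + 1) was 0.997 between cultures 1 and 2, 0.995 between 1 and 3 and 0.998 between 2 and 3, with Spearman values of 0.997, 0.995 and 0.998. These correlations are across genes, which are not independent replicates. The median SD of a gene between cultures was 0.061 on that scale. Of 13139 genes with a mean of at least 10 reads, 4303 (32.7%) varied beyond counting noise (chi-square test of Poisson heterogeneity, Benjamini-Hochberg adjusted), but for 699 of them the highest culture was at least 1.5 times the lowest. In 580 of these 699 genes culture 1 was highest, in 100 culture 3 and in 19 culture 2. Without culture 1 the test called 1458 genes, without culture 3 it called 2655 and without culture 2 it called 3899. The variation between cultures beyond counting noise had a median coefficient of variation of 3.02% over 10125 genes with at least 100 reads. A common negative binomial dispersion over the 13139 tested genes was 0.00496, a coefficient of variation of 7.04%.

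Among detected genes at 10 or more CPM, noncoding RNAs and pseudogenes dominated the largest ratios between cultures. Gm8225, a processed pseudogene, was highest in culture 3 at 11.4, 16.0 and 34.9 in cultures 1, 2 and 3 (chi-square test, adjusted p = 1.1e-109). The nuclear noncoding RNA gene Neat1 was highest in culture 1 at 273, 112 and 103, a ratio of 2.64 from the highest to the lowest culture. AI480526 (21.6, 8.83 and 8.36), the miR-17-92 host gene Mir17hg (20.3, 9.15 and 8.50), Gm13341 (17.9, 11.5 and 7.72), F630028O10Rik (25.6, 12.9 and 11.5), Gm49759 (129, 65.2 and 58.3), Slc2a4rg-ps (21.9, 10.8 and 10.3) and Mir142hg (17.0, 8.47 and 8.10) were likewise highest in culture 1, each with a chi-square adjusted p of 3.7e-31 or lower. Ppox, a haem synthesis gene, was the protein-coding gene among the 10, at 57.4, 31.5 and 27.6 (chi-square test, adjusted p = 9.6e-98). Gm8225 and Gm13341 are copies of other genes, and F630028O10Rik is annotated as antisense, so reads they share with other genes leave their values uncertain. Gm49759 lies within Pkm on the same strand of chromosome 9, and Pkm stood at 3532 CPM. Reads of Pkm transcripts may thus have been counted for Gm49759, so its value is uncertain too.

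By list, 5 of 72 list and culture pairs lay outside the central 99% of expression-matched random lists. Mitochondrially encoded mRNAs deviated from the gene mean by a median of 0.35 (log2) in culture 1 and -0.35 in culture 3, and granulocyte and monocyte genes by -0.088 in culture 1 and 0.082 in culture 3. Immediate early and heat shock genes deviated by -0.080 in culture 2. Over all detected genes, the deviation of culture 3 rose with GC content (Spearman 0.308) and fell with length (-0.157), and that of culture 2 did the opposite (-0.253 and 0.171). For culture 1 the values were -0.133 with GC content and 0.043 with length. With this trend removed, a correction chosen after the data were seen, the mitochondrial deviations were 0.25 and -0.29, and that of immediate early and heat shock genes -0.050. Those of granulocyte and monocyte genes were -0.089 and 0.098, and in culture 1 the list then lay at percentile 0.595, inside the central 99%. Sialic acid and glycan synthesis genes in culture 3 moved outside it (0.052, percentile 99.52), so 5 pairs lay outside. A gene's deviations cancel out over the cultures, so the pairs of a list are not independent. Without the correction, the number of pairs was 2 without culture 3, and 6 without culture 1 or culture 2. In these runs the deviations of the remaining cultures mirror each other, so an outlying list counts once for each of them. Of the mitochondrial genes tested, 7 of 10 varied beyond counting noise, and 7 when adjusted over the list alone. The counts were 9 of 11 and 9 adjusted over the list alone for immediate early and heat shock genes, 3 of 11 and 3 for granulocyte and monocyte genes, 14 of 17 and 15 for IL-3 signalling genes, and 5 and 4 of 21 for the inositol phosphate list. Such shares were also high in other lists, so they are not particular to IL-3 signalling. Called over all genes were 11 of 14 housekeeping, 12 of 14 MHC class I and 10 of 12 glycolysis and hypoxia genes. Of all tested genes 32.7% were called, but these include genes with a mean of only 10 reads. The chi-square test calls smaller differences in genes with more reads, such as Pgk1 at 1.02 times (adjusted p = 0.00197). List medians were 180.2 CPM for IL-3 signalling and 511 for housekeeping, against 39.7 for detected genes. The shares of these lists thus do not compare directly with 32.7%.

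**Figure D4:**
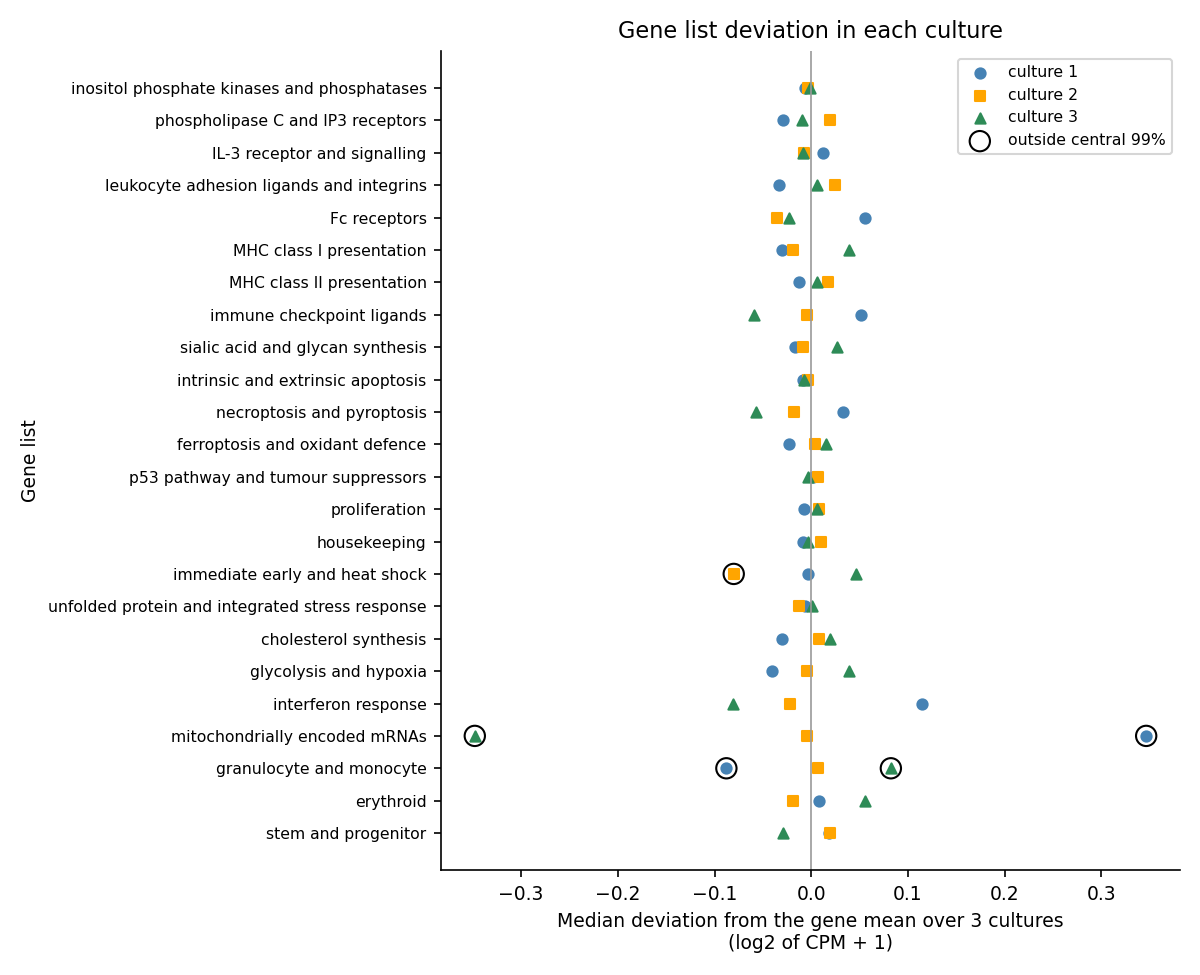
Median deviation of each list from the gene means over 3 cultures, on the log2(CPM + 1) scale, for lists with at least 5 detected members; coloured points are cultures and circles mark pairs outside the central 99% of random lists. Mitochondrially encoded mRNAs lie at 0.35 in culture 1 and -0.35 in culture 3.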

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

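The alternatives of rows as deposited, the protein-coding background, the removal of the GC and length trend and the limit of 1.5 times between cultures were chosen after the data were seen. The number of detected genes stayed between 9538 and 12214 (10991 in the report). Over the alternatives run on each, 45 of 58 summary values kept within 1.5 times of the reported count or within the spread between cultures. Of the list detections under the alternatives, 314 kept their side of the threshold, 12 lost it and 3 gained it. The granulocyte and monocyte list also lost its call against protein-coding genes, where its log2 odds changed from 1.73 to -0.038, close to 0; 45.9% of the genes in that background are detected. With that background 15 lists passed in place of 23.

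The median SD between cultures, 0.061, fell to 0.051 with a pseudocount of 5 and to 0.050 with no filter on low values, which both weigh genes near 0 differently, and ran from 0.043 to 0.062 when 1 culture was left out. The lowest Pearson correlation, 0.995, was 0.998 with no filter and 0.986 on the rows as deposited, where genes are mixed, and 0.995 to 0.998 with 1 culture left out. Genes varying beyond counting noise numbered 4303, against 699 with a ratio of at least 1.5. With 1 culture left out the number ran from 1458 without culture 1 to 3899 without culture 2. Each of these runs tests the same, smaller number of libraries, so the span between them follows which culture was left out. Outlying list and culture pairs numbered 5, also 5 with the GC and length trend removed, and 2 to 6 with 1 culture left out. In the latter runs the deviations of the remaining cultures mirror each other, so an outlying list counts once for each of them. These numbers thus do not compare directly with 5, and no other cause was tested. On the rows as deposited, read by gene identifier, Cd47 was 1318, Csf2rb 754 and Qpctl 13.2 CPM, each moved beyond its spread between cultures. Itpk1 kept within its spread when read this way. On the row with the symbol Itpk1, the authors' average corresponds to 771 CPM, 11.3 times its matched mean. Of the calls of variation in single genes, 9 were lost and 1 gained. No paired analysis was possible because the samples form 1 group. Depth limits statements on genes below 0.0936, 0.0885 and 0.0807 CPM in cultures 1, 2 and 3.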

Other observations

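The tests of the row order were chosen after the result was seen, and so were the genes and lists of the next paragraph. The other tests were chosen before their results were seen.

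Epx, which encodes eosinophil peroxidase, stood at 1769.5 ± 39, 25.3 ± 0.211 times the neutrophil peroxidase gene Mpo, and the major basic protein gene Prg2 at 206 ± 2.03. The related Prg3 (9.43 ± 0.210), Siglecf (3.93 ± 0.0783) and Ear6 (2.26 ± 0.273) were low. Il5ra (0.0104) and Ccr3 (0.0989), receptor genes of mature eosinophils, were not detected, and Ear1, Ear2 and Ear10 had no read. Pik3c2g, a lipid kinase gene, stood at 1301 ± 24.3, Emilin2 at 2541 ± 114, the insulin-like growth factor receptor gene Igf1r at 949 ± 39.1 and Mecom at 932 ± 65.2. Il3 was read at 3.71, 4.19 and 2.90 CPM in cultures 1, 2 and 3. Mtap, near Cdkn2a on chromosome 4, was at 77.9 ± 1.37 while Cdkn2a had no read.

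The first 35 rows of the deposited symbol column stand before the rest of the table, which is sorted by the authors' average from row 36 on. Itpk1 is row 18 of them, and Tubb4b, Fermt3, Ptpn2 and Vamp8 are others. Of the 35 genes, 30 were detected, with a median of 82.4 CPM and a median percentile of 72.3. What joins these genes was not tested.

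Culture 3 lay far from cultures 1 and 2 on the same deposited rows, and 2 explanations were tested. A real difference of culture 3 in its most abundant genes would leave large gaps after matching by gene, but 0 of the 120 genes above 13 then differed by more than 2 on the log2 scale, against 36 on the deposited rows. A different row order needs the gap to close, and the median difference was 0.058 after matching, beside 0.051 between cultures 1 and 2. The values are consistent with culture 3 following the order of the symbol column. How that order arose was not tested.

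Culture 1 held 75 genes at 10 or more CPM with at least 1.5 times the level of both other cultures. Culture 2 held 0 such genes and culture 3 held 8. Genes not annotated as protein-coding made up 32.0% of the 75, beside 2.07% of detected genes at that level. Gm49759, whose reads may belong to Pkm, is among them. After removal of a trend with GC content and transcript length, the set of 75 genes kept 93.2% of its median log2 difference of 0.73. The lower quartile of the corrected values was 0.61. That trend explained 3.15% of the variance of the culture 1 difference over detected genes. The set was picked for that difference, so most of it was bound to remain and the test cannot decide on this explanation. A list of 12 nuclear-retained or intron-detained transcripts, written after Neat1 and similar transcripts had been seen to be highest in culture 1 but before the values of its own members were seen, had a median of 0.42 in culture 1 against the others, percentile 100 among 10000 expression-matched random lists, with 11 of 12 members highest in culture 1. The exception, Kcnq1ot1, is with Malat1 1 of the 2 noncoding RNAs on the list, and it was lowest in culture 1 (11.83, 15.29 and 12.96 CPM in cultures 1, 2 and 3), against a rise of all nuclear RNA. The list members Rsrp1 and Luc7l3 also belong to the 75 genes, so the list is not independent of that set. A larger share of some nuclear-retained transcripts in culture 1 is a candidate explanation that stays open; whether it came from the cells or from RNA extraction cannot be read from these libraries, and no biological explanation was tested.

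Mitochondrially encoded mRNAs were highest in culture 1 and lowest in culture 3, by a median log2 difference of 0.70 over 7 genes at 10 or more CPM. After the GC and length trend was removed 79.2% of it was kept, with a lowest corrected value of 0.19. The trend as fitted over all detected genes thus does not account for the whole difference. It explained 6.56% of the variance of culture 1 against culture 3. The mitochondrial list was taken up because it deviated most, so part of its difference was likely to remain. Nuclear-encoded respiratory chain genes did not move with them: their median was -0.075 over 15 genes, with an upper quartile of -0.046. A difference in mitochondrial RNA content or in its yield at extraction may remain, and neither was tested.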
